A study of Mus musculus with 3 samples.

How the data were processed

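Dorsal midline tissue of C57BL/6J mouse embryos was dissected and dissociated, and 3′ libraries were made with 10x Genomics v3 chemistry; about 20000 cells were loaded per library with 10000 as the target, per the labels. The wild-type libraries came from 1 suspension of PGKCre;Rosa26YFP embryos at E11.5 and Wnt3aCre;Rosa26tdTomato embryos at E12.5. They were treated as technical repeats, averaged and counted as 1 sample. The authors aligned reads to mm10 and deposited UMI counts per gene and barcode. Cell Ranger 3.1.0 is named for all libraries per the submitters' processing notes, and per the file headers it was 3.1.0 for the wild type and 6.0.0 for the knockout. The annotation release is not given in the sources used here. The wild-type feature set held 28001 features, 3 of them transgene sequences, and the knockout set 32285. The 27040 features with an Ensembl ID in both sets were kept, with 99.8%, 99.8% and 99.2% of the UMIs. Left out were 961 features of the wild type and 5245 of the knockout, and 1227 kept features had a different symbol in the 2 sets. Gene positions came from GENCODE vM21 on GRCm38.

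Every deposited barcode had at least 500 UMIs, and there were 12426, 10399 and 20256 of them. Cells needed at least 1000 genes, 2000 UMIs and at most 10% mitochondrial UMIs, which 9468, 8158 and 15375 met. Doublets were scored by the share of simulated doublets (2 per cell, 30 principal components) among the neighbours, and the top 0.8% per 1000 barcodes were removed: 941, 679 and 2491 cells (9.94%, 8.32% and 16.2%). The rest, 8527, 7479 and 12884 cells, was used.

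Counts were log-normalised to 10000 per cell. The 2000 most variable genes, chosen in 20 expression bins without any gene of the fixed lists and without mitochondrial, ribosomal or haemoglobin genes, were scaled within each genotype and clipped at 10. Leiden clustering at resolution 1 used 40 components (20 within neurons) and 20 neighbours. A cluster was named after a marker class if the mean log2 fold of its markers was at least 1, with at least 3 markers at 2-fold or more. Neuron sub-clusters were called Cajal-Retzius-like if their Cajal-Retzius score exceeded the pallial score by 1 (log2). Scaling within genotype was settled after a first joint clustering had split cells by library, and the margin after the sub-clusters had been seen; without it all neuron sub-clusters took that name. The 17 marker classes, 21 gene lists, cell filters and rule for naming genes were set before the data were examined. Clustering under alternative settings depended on the arithmetic of the processor in a few cells, so the instruction set was fixed for every run.

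UMIs were summed per class and library and divided by the library's class total. Each CPM was given an exact Poisson interval, each share an exact Clopper-Pearson interval and each ratio an interval conditional on the summed counts, all at 95%. Folds on the log2 scale used the mean of the wild-type libraries and a pseudocount of 1 CPM. A gene with 0 UMIs on a side was given a bound from a floor of 3 counts over the group, and genes with 1 to 3 UMIs a ratio with its interval. Genes were named by a fixed rule: an Ensembl ID in all 3 libraries, at least 50 UMIs and 20 CPM on the higher side, and at least 2-fold in the same direction against each wild-type library with intervals that did not overlap. Mitochondrial, ribosomal, haemoglobin and sex-linked genes and predicted genes with Gm-number or Rik names were left out. The 12 highest and 12 lowest were taken, with Gmnc always and up to 4 members per list. In neurons 4 of the 12 lower and 12 of the 12 higher genes were off in the same direction by 2-fold in a control class (hem progenitor-like cells, unnamed clusters or cells outside the neural lineages), so a second version without such genes, made after this was seen, is what the text names.

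The lists were multiciliation regulators, deuterosome and centriole amplification, motile cilia components, Cajal-Retzius identity, Cajal-Retzius naming markers, other pallial neurons, subplate, p53 targets and cell death, S phase, G2 and M phase, hem signalling, Notch, axon guidance and adhesion, ion channels and synapse, choroid plexus function, early and late timing, dissociation stress, hypoxia and glycolysis, haemoglobin, and sex-linked genes. Deup1, Trp73, Cdkn1a, Nfia and Nfib each stood in 2 lists. The values of 1 list member, and a test built on them, are not reported here. Each list median was placed among the medians of 10000 random lists drawn from the 50 genes next in expression on each side of every member, as a description and not a test. The maturation score was the mean log expression of neuron markers minus that of neural progenitor markers in cells thinned to 4000 UMIs, a depth that left out 2.08%, 2.87% and 9.48% of cells. Its 10 bins were deciles of wild-type hem progenitor-like, intermediate progenitor-like and Cajal-Retzius-like cells.

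The naming rule was tested on simulated data, Poisson counts drawn from the pooled wild-type proportions at the depth of each library, with 200 genes changed and 26840 unchanged. Of 40 genes per fold, all 40 were recovered at 3-, 4- and 8-fold in each of 5 classes. At 2-fold 14 were recovered in neurons, 9 in Cajal-Retzius-like neurons, 8 in intermediate progenitor-like, 14 in hem progenitor-like and 13 in choroid plexus-like cells, none at 1.5-fold, and no unchanged gene met the rule. Changed genes were drawn from well-expressed genes only. The simulated libraries held counting error alone, whereas the real wild-type libraries differed beyond it (chi-square per degree of freedom 3.90). The simulation therefore does not show how often the rule names genes because of feature sets, stage or other differences between libraries. Alternatives covered a filter of 2000 genes and 5% mitochondrial UMIs, doublets kept, resolutions of 0.5 and 2, clustering with the list genes, classes from the wild type alone, median-ratio and TMM scaling, thinned cells, a pseudocount of 5 CPM, stricter list members, 5 bins and each wild-type library alone. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and edgeR 4.0.16 in R 4.3.3 for TMM only.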

Results

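Single cells from the dorsal midline of the embryonic mouse telencephalon, the cortical hem and its surroundings, were profiled with droplet 3′ RNA sequencing in wild-type and Gmnc-/- embryos. The hem gives rise to Cajal-Retzius neurons and adjoins the choroid plexus, whose epithelium carries motile cilia. The wild type consisted of 2 libraries drawn from 1 suspension, which pooled 4 embryos at E11.5 and 4 at E12.5. The knockout was 1 library from 4 pooled embryos at E12.5. The libraries held 148073906 and 139978761 UMIs in the wild type and 259403297 in the knockout, with a median of 11657, 12851 and 8720 UMIs per cell over 8527, 7479 and 12884 used cells. Each genotype was 1 suspension, so there were no biological replicates and no test was run. Stage, dissection and processing could not be separated from genotype. The wild-type embryos carried Cre and reporter transgenes (PGKCre;Rosa26YFP or Wnt3aCre;Rosa26tdTomato). The knockout feature set lacks these sequences, so the counts cannot tell whether the transgenes differ between genotypes. Expression is given in CPM, UMIs scaled to the total of the class and library, in wild-type library 1, wild-type library 2 and the knockout, in that order. Bracketed ranges are 95% intervals that cover counting error only. Medians of gene lists were taken over all members with a UMI, and numbers of members refer to those with at least 50 UMIs and 20 CPM on the higher side, a fold of 2 being the limit for lower or higher.

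The first question was how alike the wild-type libraries were. Their summed counts had a correlation of 0.9998 over 27040 genes on the log scale, against 0.986 between wild-type library 1 and the knockout. The largest difference of a gene deep enough for comparison ranged from 0.40 (log2) for Phf2 in hem progenitor-like cells, over 0.72 for Atpaf1 in Cajal-Retzius-like neurons, to 0.85 for Serpine2 in intermediate progenitor-like cells. Chi-square per degree of freedom was 3.90 between the wild-type libraries, so these repeats differed beyond the counting error that the intervals cover. Hem progenitor-like cells made up 19.3%, 19.7% and 15.1% of the cells in the 3 libraries, choroid plexus-like cells 14.5%, 14.2% and 11.4%, intermediate progenitor-like cells 6.45%, 6.57% and 7.47%, and neurons 11.6%, 12.2% and 8.04%. Clusters without a name from the markers held 44.9%, 43.9% and 53.7%, and erythroid cells 2.24%, 2.31% and 1.73%.

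The next question was which wild-type cells carried the multiciliation genes. Gmnc, which encodes a Geminin-related coregulator at the head of the multiciliation program, was most abundant in Cajal-Retzius-like neurons (199 [187 to 212] and 185 [173 to 197] CPM in the wild-type libraries) and intermediate progenitor-like cells (173 [162 to 183] and 155 [145 to 165]). It stood at 67.2 [63.3 to 71.3] and 72.2 [68.0 to 76.5] CPM in choroid plexus-like cells and at 9.81 [8.53 to 11.2] and 14.9 [13.4 to 16.6] in hem progenitor-like cells. Erythroid cells, taken as a measure of free RNA, had 0.636 and 0.925 CPM. Mcidas, a Geminin-related partner of E2f factors, and Ccno, a cyclin-like protein needed for centriole production, were both highest in Cajal-Retzius-like neurons: Mcidas had 227 and 230 CPM there and 46.4 and 55.7 in choroid plexus-like cells, and Ccno had 629 and 622 and 113 and 125. Trp73, a p53 family transcription factor, had 347 and 359 CPM in Cajal-Retzius-like neurons and 3.76 and 3.70 in hem progenitor-like cells.

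The fixed list of multiciliation regulators had a median log2 ratio of 2.89 in wild-type Cajal-Retzius-like neurons over hem progenitor-like cells, with 6 of 9 members above 20 CPM at least 2-fold higher. That median had a wide interval across members (0.23 to 3.85) and ranged from 0.25 to 2.95 over other settings. In choroid plexus-like cells the median was 2.47, again with 6 of 9. Genes that build the motile axoneme were more a property of the choroid plexus-like cells (median 3.74, 21 of 22 members at least 2-fold higher) than of the Cajal-Retzius-like neurons (1.68, 9 of 11). Dynlrb2, a dynein light chain, had 171 and 188 CPM in the former and 54.6 and 51.5 in the latter, and Rsph1, a radial spoke protein, 118 and 127 and 33.3 and 36.4. The choroid plexus-like level of Dynlrb2 came mainly from cluster 13 (685 and 667 CPM in 306 and 289 cells), while the larger cluster 1 had 19.6 and 16.5 CPM, below the Cajal-Retzius-like level. Foxj1, the transcription factor that drives motile ciliogenesis, had 273 and 309 CPM in choroid plexus-like cells (796 and 805 in cluster 13, 118 and 132 in cluster 1) and 274 and 261 in Cajal-Retzius-like neurons. Deuterosome and centriole amplification genes had medians of 0.45 and 0.81, with Deup1, a deuterosome scaffold, at 117 and 135 and 86.3 and 90.5 CPM. In neurons outside the Cajal-Retzius-like clusters the 3 lists had medians of −0.35 (regulators), −0.41 (deuterosome) and −0.57 (motile cilia).

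The main comparison asked how neurons differed between genotypes. UMIs of the targeted gene remained: Gmnc had 29.4 [28.6 to 30.3], 30.7 [29.8 to 31.7] and 41.5 [40.7 to 42.2] CPM over whole libraries and 117 [110 to 124], 110 [103 to 117] and 35.4 [31.8 to 39.4] in neurons. The reads come from the 3′ end of the transcript and the deleted part is not given in the sources used here, so these counts test nothing about the genotype. Ccno had 371 [359 to 384], 361 [349 to 374] and 0 [0 to 0.383] CPM in neurons, at least 1175-fold lower in the knockout, and Mcidas 132 [125 to 140], 133 [126 to 141] and 0 [0 to 0.383], at least 426-fold lower. Trp73 had 203, 205 and 0.104 CPM, with 1 UMI in the knockout (1963-fold [352 to 77562] lower). Cdkn1a, a cyclin-dependent kinase inhibitor that marks Cajal-Retzius neurons, was 82.3-fold [69.6 to 97.9] lower (1209, 1166 and 14.4 CPM), and Lhx1, a LIM homeodomain factor, 15.1-fold [12.6 to 18.2] lower (199, 199 and 13.2).

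On build GRCm38, Gmnc (ENSMUSG00000068428) lies on chromosome 16 at 26913553 to 26991652. Ccno (ENSMUSG00000042417) and Mcidas (ENSMUSG00000074651) are neighbours on chromosome 13, at 112987802 to 112990777 and 112993845 to 113000394. Trp73 (ENSMUSG00000029026) spans 154056253 to 154140208 on chromosome 4, Cdkn1a (ENSMUSG00000023067) 29090976 to 29100727 on chromosome 17, and Lhx1 (ENSMUSG00000018698) 84518284 to 84525535 on chromosome 11.

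Of the multiciliation regulators, 8 were measured well enough in neurons; 7 were at least 2-fold lower in the knockout and none was 2-fold higher. Of these, E2f4 was about as much lower in hem progenitor-like cells (log2 −1.30 in neurons and −1.03 there). The list had a median log2 fold of −2.31, or −2.59 with genes of 0 counts placed at their bound, and no random list matched on expression reached as low a median (percentile 0.00 of 10000). Without Gmnc itself the median was −2.59. Foxj1 had 159, 151 and 3.32 CPM (46.8-fold [33.0 to 68.5] lower) and Myb, a transcription factor active in early multiciliated cells, 31.4, 34.1 and 2.80. Of the deuterosome genes 5 of 8 were lower and none higher (median −0.94, percentile 0.01), among them Deup1 at 49.5, 51.7 and 0.208 CPM with 2 UMIs in the knockout (244-fold [67.3 to 2015]). All 6 well-measured motile cilia components were lower (median −1.93, percentile 0.00).

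Cajal-Retzius identity genes were level as a group in neurons. Of 19 well-measured members 6 were lower and 3 higher, with a median of 0.01 (percentile 72.0). Lhx1, Cdkn1a and Trp73 were among the lower ones. The naming markers, kept apart, had a median of −0.08: Reln, the extracellular signal of these neurons, had 111 [104 to 118], 103 [96.8 to 110] and 118 [111 to 125] CPM, Nhlh2 469, 509 and 670 and Ebf2 446, 436 and 358, while Calb2, a calcium-binding protein, was 5.60-fold [5.28 to 5.97] higher (89.8, 64.0 and 431). p53 targets and cell death genes were lower in 8 of 13 members and higher in 2 (median −1.19, percentile 0.00), with Phlda3, a p53-induced Akt inhibitor, at 178, 161 and 3.95 CPM. Genes of other pallial neurons (median 0.38, 2 of 21 lower and 5 higher), axon guidance and adhesion (0.24, 1 and 3 of 18) and ion channels and synapse (0.34, 0 and 3 of 14) stood above the median of all 6642 well-measured genes, which was −0.14. This was not particular to neurons. In hem progenitor-like cells pallial genes had a median of 0.20, axon guidance genes 0.42 and ion channel genes 0.29. In unnamed clusters these were 0.13, 0.40 and 0.33. Median-ratio scaling moved that median by 0.13 and TMM scaling by 0.11. Haemoglobin genes were higher in all 7 members (median 3.64), as in each of the other classes compared.

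Beyond the multiciliation genes, the genes furthest apart in neurons without a like shift in a control class, where most were too shallow to judge, were Shisa8 (132, 137 and 0.208 CPM, 2 UMIs in the knockout), Plvap, an endothelial diaphragm protein (71.3, 60.8 and 0.104), and Cav2, a caveolar coat protein (55.0, 58.0 and 0.104), each with 1 UMI in the knockout, on the lower side. On the higher side were Klf12 (0.799, 1.56 and 46.8), Nrcam, a neuronal adhesion molecule (14.0, 10.1 and 94.0), Tac1, the substance P precursor (5.48, 5.89 and 38.3), Hrk, a BH3-only death gene (9.47, 7.89 and 51.4), and Gabra2, a GABA receptor subunit (9.13, 9.01 and 43.1). The naming rule as first fixed also took Srp54c (−6.44, log2) and Ptp4a1 (−6.43) as lower and Nme2 (8.92) and Atp6v0c (7.95) as higher, but these and 12 others were off the same way in control classes such as hem progenitor-like cells.

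The same comparison was then made within Cajal-Retzius-like neurons, 627 and 569 cells in the wild type and 552 in the knockout. The wild-type cells sat mainly in sub-clusters 1, 3 and 5 (242, 169 and 156 cells in library 1, 208, 171 and 141 in library 2) and the knockout cells in sub-cluster 0 (528, against 24 and 20). A margin set after the clusters had been seen left 36.4%, 37.9% and 46.7% of neurons outside the class. Ccno had 629 [607 to 651], 622 [600 to 644] and 0 [0 to 0.738] CPM, at least 1042-fold lower in the knockout, and Mcidas 227 [213 to 240], 230 [217 to 243] and 0 [0 to 0.738], at least 380-fold lower. Trp73 had 347 [331 to 364], 359 [343 to 376] and 0.200 [0.00507 to 1.12] CPM, with 1 UMI in the knockout (1764-fold [317 to 69724]). Cdkn1a was 101-fold [83.2 to 124] lower (2067, 2024 and 20.2 CPM) and Lhx1 13.9-fold [11.6 to 16.8] lower (346, 350 and 25.0). Gmnc had 199 [187 to 212], 185 [173 to 197] and 57.8 [51.4 to 64.9] CPM, a lower level that, as in all neurons, depended on where class borders were drawn.

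The multiciliation regulators had a median of −2.99 in these neurons (percentile 0.00, and −4.78 to −1.44 over other settings), or −3.27 with genes of 0 counts at their bound, with 7 of 8 members lower. Deuterosome genes were lower in 8 of 11 (median −1.39, and −1.56 to −0.63 over other settings), including Deup1 (86.3, 90.5 and 0.200 CPM, 1 UMI in the knockout, 442-fold [79.1 to 17465]) and Stil, a centriole duplication protein (22.7, 24.4 and 1.60, 14.7-fold [7.34 to 34.5]). All 11 motile cilia components were lower (median −2.42, and −3.53 to −1.20 over other settings): Tekt1, a structural tektin, had 73.6, 86.6 and 1.80 CPM and Dynlrb2 54.6, 51.5 and 0.200, with 1 UMI in the knockout (265-fold [47.4 to 10487]). p53 targets were lower in 11 of 15 members and higher in 2 (median −1.68), the lower ones including Phlda3 (310, 279 and 4.60), Perp (62.6, 58.4 and 1.40) and Mdm2, the ubiquitin ligase of p53 (238, 238 and 61.0), while the apoptosis effector Bax was near level (329, 321 and 300).

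Within Cajal-Retzius identity 5 of 19 members were lower and 4 higher, and the median was 0.00 (percentile 79.4). Beside Lhx1, Cdkn1a and Trp73, Cacna2d2, a calcium channel subunit, was lower (317, 308 and 90.9 CPM), and Onecut2, a cut-homeodomain factor, was 4.79-fold higher (18.1, 16.7 and 83.3). Tbr1, a T-box factor of early glutamatergic neurons, was near level (484 [465 to 503], 480 [462 to 500] and 448 [429 to 467]). The hem signalling genes (Wnt and Bmp) were lower in 5 of 10 members (median −1.21, and −1.37 to −0.09 over other settings), with Wnt7b at 382, 361 and 67.6 and the Bmp target Id1 at 188, 179 and 19.0 CPM. Subplate genes had a median of 0.47, with 2 of 3 members higher.

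Genes of other pallial neurons were compared next in the Cajal-Retzius-like clusters. The nuclear factors I, which act in neuronal maturation, were higher: Nfix 4.96-fold [4.67 to 5.28] (152, 141 and 726 CPM), Nfib 3.47-fold [3.38 to 3.57] (789, 740 and 2654) and Nfia 2.91-fold [2.78 to 3.04] (329, 319 and 942). Of the 21 well-measured list members 7 were higher and 2 lower, Pou3f1 (17.6-fold [13.2 to 23.9]) and Pou3f2 (13.2-fold [10.2 to 17.4]), POU factors of upper-layer neurons. The list median was 0.42 (percentile 99.94), against −0.17 for all 6863 well-measured genes, which median-ratio scaling moved by 0.17 and TMM by 0.15. It was above 0 in the other classes too. Choroid plexus-like cells had 0.33 (percentile 99.8), the remaining neurons 0.23 (98.7) and hem progenitor-like cells 0.20 (97.1). Intermediate progenitor-like cells had 0.14 (97.0) and unnamed clusters 0.13 (95.8). Late embryonic timing genes, which share Nfia and Nfib with this list, had a median of 1.19 (5 of 7 higher and 1 lower, percentile 100). In hem progenitor-like cells the log2 folds were 1.14 for Nfia, 0.89 for Nfib and 0.70 for Nfix, of which only Nfia was 2-fold higher.

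Outside the lists, the largest folds in Cajal-Retzius-like neurons, again without a like shift in a control class, included Cav2 with 95.1, 102 and 0 CPM (at least 164-fold lower), Plvap with 122, 106 and 0.200 (1 UMI in the knockout), and E2f7, an atypical E2F repressor, with 179, 176 and 2.20. Shisa8 had 231, 237 and 0.400 CPM and Tfap2b, an AP-2 factor, 60.6, 82.8 and 0.400, each with 2 UMIs in the knockout. Higher in the knockout were Tac1 (1.81, 0.787 and 55.0), Klf12 (0.803, 0.984 and 56.0) and Nrgn, a postsynaptic calmodulin-binding protein (4.61, 3.54 and 86.7). Ion channel and synapse genes had a median of 0.62, with 5 of 14 members higher, among them Slc17a7, a vesicular glutamate transporter (2.41, 1.77 and 37.4, 17.9-fold [11.4 to 29.7]); the median was −0.47 when only clusters with at least 20 cells of each genotype were used. Axon guidance genes had 0.32, with 6 of 18 higher, such as Nrcam (7.02, 5.31 and 100), and 1 lower, a median below that of hem progenitor-like cells (0.42).

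**Figure D1:**
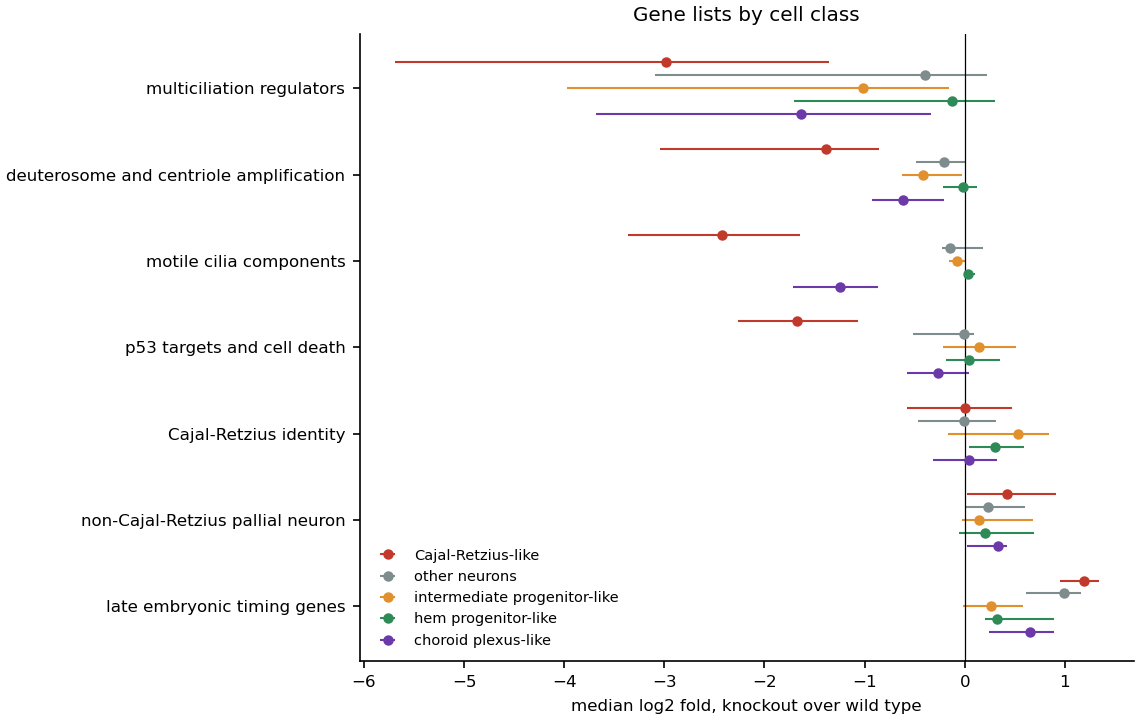
Median log2 fold of 7 fixed gene lists, knockout over wild type, over all members with a UMI in 5 cell classes (1 knockout library, 2 wild-type libraries averaged); bars are order-statistic 95% intervals of the median across member genes. Multiciliation regulators (−2.99) and motile cilia components (−2.42) had their lowest medians in Cajal-Retzius-like neurons, and late timing genes (1.19) their highest.

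The share of Cajal-Retzius-like cells among neurons was 63.6% [60.5 to 66.6], 62.1% [58.9 to 65.3] and 53.3% [50.2 to 56.4], a knockout value 9.57 percentage points under the wild-type mean. This order did not hold when cells were clustered in other ways, so the shares give no direction. In the remaining neurons Ccno had 31.5, 22.3 and 0 CPM (at least 41.5-fold lower), with a UMI in only 23 of 359 and 14 of 347 wild-type cells, and Gmnc had 7.67, 11.3 and 11.2. The wild-type cells among them sat mainly in sub-clusters 2 and 4 and the knockout cells in 6 and 7, so their values compare different clusters. The remaining neurons of the knockout had higher Hrk (4.76, 3.58 and 66.9), and Mef2c, a neuronal transcription factor (5.29, 4.09 and 28.3). Regulators of multiciliation had a median of −0.39 there, with Ccno and E2f4 as the 2 of 3 lower, E2f4 being lower in hem progenitor-like cells as well, Cajal-Retzius identity genes −0.01 and late timing genes 0.99.

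The timing of these genes was followed along a maturation score that rose from hem progenitor-like cells over intermediate progenitor-like cells to Cajal-Retzius-like neurons, in 10 bins. In the wild type Gmnc was highest in bin 8 (262 and 244 CPM), ahead of Mcidas and Ccno, which were highest in bin 9 (202 and 200 CPM; 605 and 578 CPM), and of Trp73 and Cdkn1a, which were highest in bin 10 (317 and 308 CPM; 2049 and 2025 CPM). In wild-type library 1 Gmnc was nearly as high in bin 9 (256 CPM) as in bin 8, so its lead over Mcidas and Ccno rested mainly on library 2. The bin where Gmnc, Mcidas and Ccno summed to their highest level was centred on the 85th percent of wild-type cells. Knockout Gmnc was also highest in bins 8 and 9, with 113 [101 to 127], 292 [268 to 317], 291 [270 to 313] and 68.6 [61.2 to 76.6] CPM in bins 7 to 10, against 183, 262, 256 and 34.6 in wild-type library 1 and 181, 244, 180 and 40.7 in library 2. It was thus lower in bin 7 and higher in bin 10. Ccno had 0 UMIs in each of these 4 bins, and Mcidas and Trp73 had at most 1 UMI per bin (0.522 CPM in bin 8 and 0.419 in bin 9). Lhx1 was at 170 and 229 CPM in bin 9 and 564 and 536 in bin 10 of the wild type, and at 56.6 and 56.3 in the knockout. In the earliest bins, 1 to 3, Gmnc was higher in the knockout (19.4, 25.0 and 23.1 CPM against at most 7.03 in the wild type). Bins 8 and 9 held few knockout cells named Cajal-Retzius-like (1.92% and 29.1%, against 40.7% and 67.6% in wild-type library 1).

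**Figure D2:**
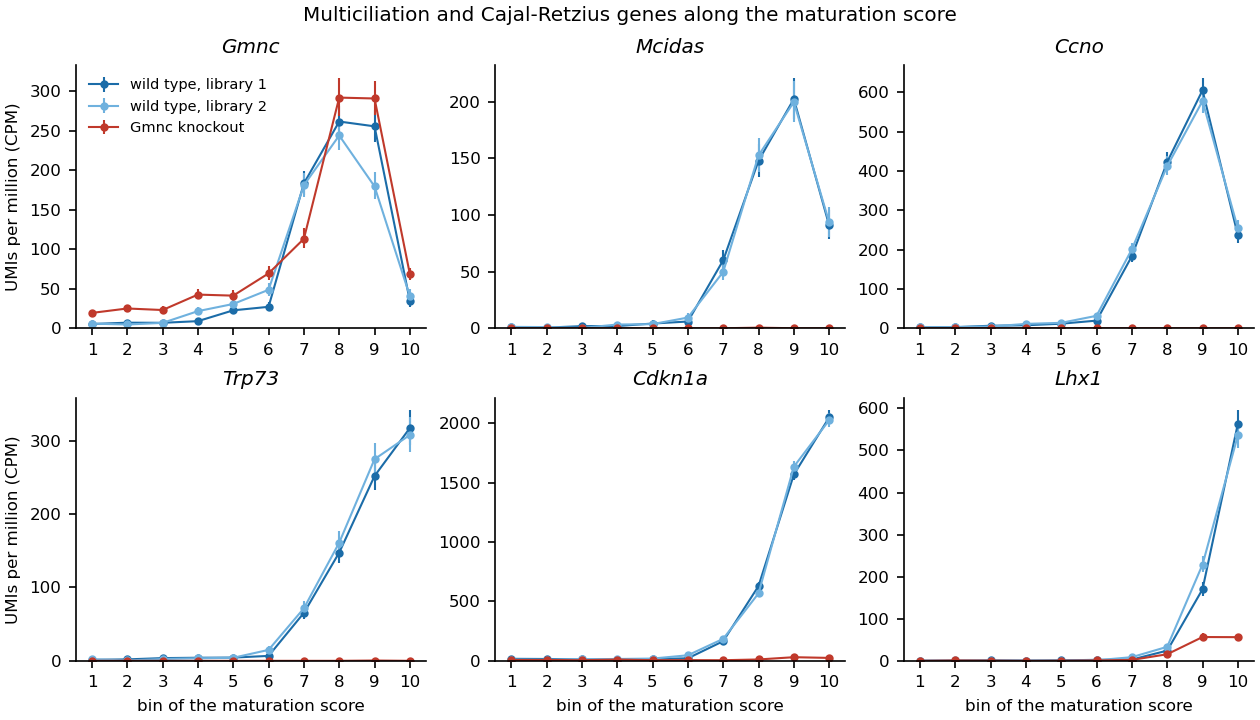
CPM of Gmnc, Mcidas, Ccno, Trp73, Cdkn1a and Lhx1 in 10 bins of the maturation score, from hem progenitor-like (1) to Cajal-Retzius-like (10), in 2 wild-type libraries and 1 Gmnc knockout library; bars are exact Poisson 95% intervals. Gmnc reached 292 CPM in bin 8 of the knockout, while Ccno, at 605 and 578 CPM in bin 9 of the wild type, had 0.

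Intermediate progenitor-like cells were compared to see how early the difference appeared. Gmnc had 173 [162 to 183], 155 [145 to 165] and 239 [228 to 251] CPM, a log2 fold of 0.54 that ranged from −2.79 to 0.73 over other settings and so gives no direction. Ccno had 103 [95.3 to 112], 105 [97.3 to 114] and 0 [0 to 0.523] (at least 245-fold lower) and Trp73 35.1, 35.4 and 0 (at least 82.9-fold lower). Mcidas had 27.3, 21.1 and 0.142 CPM, with 1 UMI in the knockout (170-fold [30.4 to 6766]). Of the regulators 6 of 9 were lower (median −1.02, percentile 0.00, and −2.22 to −0.29 over other settings), while none of the 7 deuterosome genes was 2-fold off (−0.41). Genes of G2 and M phase were lower in 13 of 20 members (median −1.27, and −1.55 to −0.60 over other settings), such as Cdc20, an activator of the anaphase-promoting complex (277, 277 and 70.9), and S phase genes in 2 of 18, with 1 higher (median −0.75). S phase and G2 and M phase genes also stood below 0 in unnamed clusters (medians −0.54 and −0.28). Neurog1, a proneural factor, was lower (140, 123 and 36.6), and Stmn2, a neuronal microtubule regulator, higher (46.0, 59.9 and 221). Notch genes had a median of −0.50, with 1 of 8 lower, and axon guidance genes 0.33, with 4 of 13 higher.

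Hem progenitor-like cells, 1648, 1474 and 1944 in number, were compared as the source of the other lineages. Gmnc was 2.68-fold [2.40 to 2.97] higher in the knockout (9.81 [8.53 to 11.2], 14.9 [13.4 to 16.6] and 33.2 [31.1 to 35.4] CPM), and the low wild-type level of Ccno was not matched (7.23, 8.78 and 0.0371, 1 UMI in the knockout, 216-fold [38.6 to 8572]). The regulators had a median of −0.12 (percentile 13.8), or −0.44 (percentile 0.00) without Gmnc, with 1 of 5 well-measured members lower, E2f4 (53.4, 51.5 and 25.3), and Gmnc the 1 higher, the deuterosome genes −0.01 and the motile cilia components 0.04. S phase genes had a median of −0.65 (percentile 0.00) with 1 of 19 higher and 2 lower, the latter including Rrm2, a ribonucleotide reductase subunit (287, 300 and 135), and G2 and M phase genes −0.44 with none of 20 lower. Hem signalling genes (Wnt and Bmp) had a median of −0.14, with 1 of 15 higher: Bmp6, a secreted Bmp ligand (3.19, 2.59 and 30.5). Late timing genes had a median of 0.32, with 3 of 11 higher. Outside the lists Htra1, a secreted protease, was higher (0.376, 0.312 and 22.2) and Large2, a glycosyltransferase, lower (25.4, 28.4 and 6.90).

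Choroid plexus-like cells, the multiciliated lineage of the tissue, were compared last. Gmnc was 2.88-fold [2.73 to 3.03] higher in the knockout (67.2 [63.3 to 71.3], 72.2 [68.0 to 76.5] and 200 [194 to 207] CPM). Ccno had 113 [108 to 118], 125 [119 to 130] and 0.343 [0.138 to 0.707] (346-fold [168 to 861] lower), Mcidas 46.4, 55.7 and 0 (at least 347-fold lower) and Trp73 25.7, 30.3 and 0.0490 (1 UMI in the knockout, 572-fold [102 to 22545]). Foxj1 was retained at a lower level (273, 309 and 69.5, 4.19-fold [3.95 to 4.42] lower). The regulators had a median of −1.63 (percentile 0.00), or −2.45 with genes of 0 counts at their bound, with 6 of 9 lower and Gmnc the 1 higher. Deuterosome genes were lower in 3 of 10 (median −0.61), with Deup1 at 117, 135 and 0.735 CPM (171-fold [104 to 306]), and motile cilia components in 13 of 22 (median −1.24), such as Dynlrb2 (171, 188 and 21.9) and Fam183b (25.2, 27.3 and 1.86).

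The wild-type cells of this class formed 2 clusters and the knockout cells 1. Cluster 1 held 931, 770 and 1467 cells, and cluster 13 held 306 and 289 wild-type cells and none of the knockout. In cluster 1 Ccno had 43.4, 45.9 and 0.343 CPM, Foxj1 had 118, 132 and 69.5, Deup1 had 17.4, 11.9 and 0.735, and Dynlrb2 was near level (19.6, 16.5 and 21.9). In cluster 13 the wild type had 348 and 345 CPM of Ccno, 796 and 805 of Foxj1, 454 and 480 of Deup1 and 685 and 667 of Dynlrb2. The class folds of Dynlrb2 and Foxj1, much of that of Deup1, and the lower motile cilia median therefore rested largely on cluster 13. Without it the motile cilia median was 0.43, but leaving it out removed wild-type cells only. Ttr was at 30116 and 29803 CPM in cluster 13, at 11903 and 13314 in wild-type cluster 1 and at 39632 in the knockout. Cluster 1 thus did not match the genotypes on this marker, and its values do not show whether cilia genes differ among like cells. Cilia genes outside the fixed lists took part in the clustering, so the empty knockout cluster is no count of missing cells.

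Genes of choroid plexus function were higher in the knockout in 5 of 11 members and lower in none (median 0.75, percentile 100). The list was also above 0 in hem progenitor-like cells (median 0.33, percentile 99.9) and unnamed clusters (0.18, percentile 99.4). Enpp2, a secreted lysophospholipase, was 8.69-fold [7.87 to 9.68] higher (12.1, 14.9 and 118 CPM), Slc4a5, a bicarbonate cotransporter, 7.43-fold [6.44 to 8.67] (6.04, 7.57 and 50.6) and Trpm3, a cation channel, 5.05-fold [4.93 to 5.19] (248, 263 and 1289), the last as far apart in hem progenitor-like cells (6.50-fold [5.93 to 7.15]). Ttr, the thyroid hormone carrier that named these clusters, had 11903, 13314 and 39632 CPM in cluster 1. In cluster 13, which held wild-type cells only, it had 30116 and 29803 CPM, so the gap in cluster 1 overstates that of the class. Ptgds, a prostaglandin synthase, had 5.19, 6.09 and 56.3 CPM, and G2 and M phase genes had a median of −0.62, with 4 of 20 lower.

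**Figure D3:**
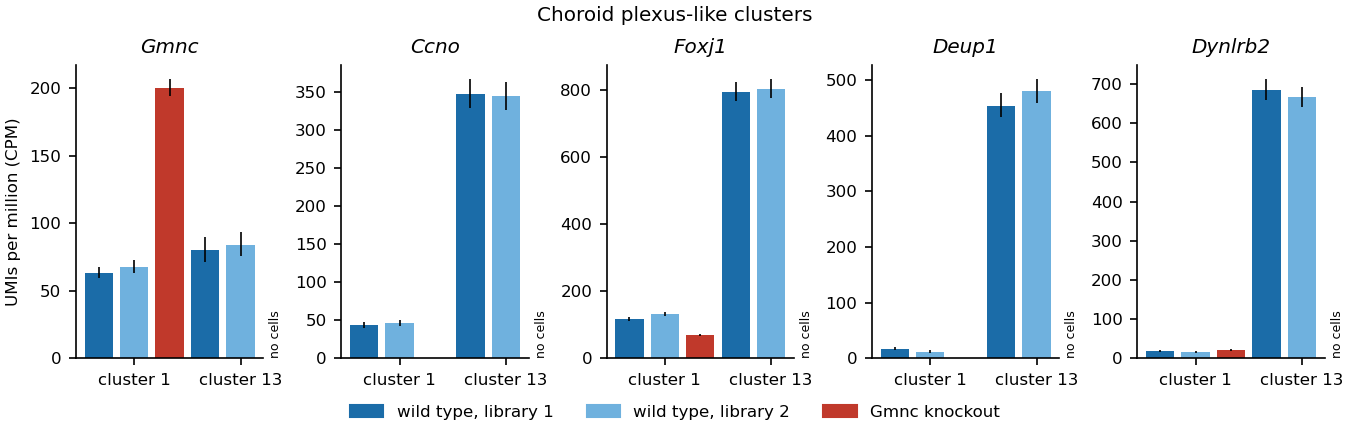
CPM of Gmnc, Ccno, Foxj1, Deup1 and Dynlrb2 in the 2 choroid plexus-like clusters, in 2 wild-type libraries and 1 Gmnc knockout library; bars start at 0 and carry exact Poisson 95% intervals. Gmnc was at 200 CPM in knockout cluster 1 against 63.5 and 67.9 in the wild type, and cluster 13, with 454 and 480 CPM of Deup1, held no knockout cells.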

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

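The tests in this part on differences between feature sets and on maturation were chosen only after the results had been seen; those on the E11.5 cells were set before their values were computed. The test of feature sets for Gmnc replaced a first version whose values had been seen.

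The wild-type libraries held transgene counts that the comparison of genotypes did not use. UMIs of dtTomato, the reporter of the E12.5 embryos, were found in 13.1% (1120 of 8527) and 13.3% (992 of 7479) of cells, UMIs of eYFP, the reporter of the E11.5 embryos, in 64.5% (5499) and 64.9% (4852), and UMIs of the IRESCRE sequence in 0.152% (13) and 0.267% (20); a count of 0 would have allowed 0.0352% and 0.0401%. dtTomato was found in 26.1% and 24.2% of hem progenitor-like cells and in 2.62% and 5.78% of erythroid cells, and IRESCRE in 0.607% and 0.95% of hem progenitor-like cells, where Wnt3a is active. eYFP was in 55.5% and 53.2% of erythroid cells (median 15686 and 17558 UMIs) and in 70.7% and 69.0% of choroid plexus-like cells, and 2.32% and 2.41% of all cells had both reporters. The knockout feature set has no such sequences, so no knockout value exists. Among Cajal-Retzius-like neurons, cells with dtTomato only had late timing genes at 0.24 (−0.21 to 0.44) and early timing genes at −0.34 (−0.71 to 0.01) relative to cells with eYFP only (median log2). In choroid plexus-like cells these were 0.06 (−0.13 to 0.08) and −0.06 (−0.32 to 0.10). All these intervals included 0, so these lists do not show how well the reporters part the stages. The reporters themselves fell mostly in separate cells. eYFP was in 198 of 1120 and 180 of 992 cells with dtTomato, against 5499 of 8527 and 4852 of 7479 of all cells. Cells with eYFP only numbered 5301 and 4672, and cells with dtTomato only 922 and 812.

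The first pattern weighed was the lower level of multiciliation genes in knockout Cajal-Retzius-like neurons. A difference between feature sets would give the same fold in hem progenitor-like cells. The 8 members measured in both classes, however, had a median difference of −2.02 (−3.07 to −0.96). They were Plk4, Sass6, Cep57l1, E2f4, Cenpj, Mns1, Foxj1 and the targeted gene Gmnc, and no median was taken without Gmnc. E2f4, at −1.36 against −1.03, was lower alike in both and is left open. Against wild-type cells with dtTomato only, the regulators were still at −3.42 (−7.88 to −1.12). Wnt3aCre drove dtTomato, so these cells were selected for the Wnt3a lineage as well as for stage, unlike the knockout cells. The value goes against the E11.5 cells as the source as far as the reporters part the stages. The timing lists did not show that they do. In Cajal-Retzius-like neurons, however, eYFP was in 14 of 109 and 14 of 89 cells with dtTomato, against 398 of 627 and 377 of 569 of all. Ccno, Mcidas and Trp73 together reached at most 0.448% of the wild-type level in the 4 highest bins. This goes against a different position along the maturation score as the source. The bins held different shares of Cajal-Retzius-like cells in the genotypes, so a different mix of cells within them is not excluded. Wild-type sub-cluster 8 had only 3.70 and 0 CPM of Ccno and 0 of Mcidas, but 241 and 234 of Trp73. For Ccno, Mcidas and Trp73 a difference between feature sets and a difference between cells cannot be told apart, because 0 of the 3 genes were deep in a class outside the hem and choroid plexus lineages. Dissection and processing, which the design does not part from genotype, stay open, and so does stage where the reporters fail to part it.

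The second pattern was Gmnc, higher in knockout hem progenitor-like and choroid plexus-like cells and lower in Cajal-Retzius-like neurons. A feature-set difference would shift Gmnc alike everywhere. Its log2 fold was 1.30 (1.10 to 1.54) larger in choroid plexus-like cells than in the bin where wild-type Gmnc was highest. That bin held different shares of Cajal-Retzius-like cells in the genotypes, so this value cannot decide. Over other settings the log2 fold was 0.92 to 1.66 in hem progenitor-like and 1.41 to 1.79 in choroid plexus-like cells. These ranges overlap, and a feature-set difference stays open. Against choroid plexus-like cells with dtTomato only, Gmnc was 2.85-fold (2.57 to 3.23) higher. In that class eYFP was in 33 of 157 and 28 of 157 cells with dtTomato, against 874 of 1237 and 731 of 1059 of all. The fold thus goes against the E11.5 cells as the source as far as the reporters part the stages. Timing genes hardly differed between the reporters there, and dtTomato also selects for the Wnt3a lineage, so finer stage stays open. The lower level in Cajal-Retzius-like neurons could come from a different mix of maturation, since in 3 of the 3 highest bins the knockout was at or above the wild-type mean. Whether the targeted allele makes a more stable transcript was not tested.

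The third pattern was the higher level of pallial neuron genes such as Nfix and Nfib in knockout Cajal-Retzius-like neurons. Against wild-type cells with dtTomato only the list median was 0.49 (0.04 to 1.15). This goes against the E11.5 cells as the source as far as the reporters part the stages, though dtTomato also selects for the Wnt3a lineage. The members Zbtb18, Prox1, Nfib, Nfia, Cux2 and Nfix had log2 folds above 0 in hem progenitor-like cells too, from 0.20 (Cux2) to 1.57 (Prox1), and only Prox1 and Nfia were 2-fold higher there. The median difference of these 6 between the classes was 0.65 (0.34 to 1.19), so a shift particular to these neurons and one shared with progenitors, from feature sets or finer stage, cannot be told apart.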

How the results depend on the processing

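The alternatives on scaling within genotype, reporter-positive cells, clusters shared by both genotypes, control classes, the score margin and the added neurons were chosen only after the results had been seen.

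No paired analysis was possible because each genotype was 1 suspension and no number links knockout to wild-type embryos. With 1 suspension per genotype nothing covers variation between embryos, and depth limits the folds of genes absent from the knockout to bounds. Of the planned and added tests of the main results 125 stayed the same, 10 moved and 3 reversed; among the other values 478 stayed, 287 moved and 11 reversed, and the cause was not tested. Correlation between wild-type libraries was 0.9995 over genes with at least 50 UMIs. At resolution 2 the regulators in neurons had a median of −1.18, Gmnc was at 0.99 in Cajal-Retzius-like neurons and 1.45 in neurons, Lhx1 in intermediate progenitor-like cells at −0.42, the share difference at 16.7 percentage points and the bin of highest multiciliation expression at the 75th percent. With classes from the wild type alone the list and gene values were −1.09, 1.20, 1.43 and −1.63. The share difference was then −4.78 percentage points, the direction of the main result. The bin was again 75, as it was when list genes joined the clustering or other neurons were added. Clusters with at least 20 cells of each genotype gave 0.43 for motile cilia components in choroid plexus-like cells, which leaves out the wild-type cluster 13, −0.47 for ion channels in Cajal-Retzius-like neurons, and 0.66 for Gmnc both there and in neurons. Genes scaled over all cells gave 0.0286 for Gmnc in neurons and 4.82 points for the share, which was 35.4 at resolution 0.5, −23.9 with dtTomato cells only and 0 without the margin. Leaving out genes off in a control class left 8 of the 24 named genes of neurons. With either wild-type library alone the regulators were at −2.42 to −2.18 in neurons and −1.66 to −1.60 in choroid plexus-like cells, Cajal-Retzius identity at −0.13 to 0.11 in neurons and −0.08 to 0.08 in Cajal-Retzius-like neurons, pallial genes at 0.43 to 0.46, and the share at −10.3 to −8.84. Over all alternatives Ccno in Cajal-Retzius-like neurons ranged from −9.38 to −6.83, Trp73 from −8.34 to −6.11, p53 targets from −1.87 to −1.19, pallial genes from 0.27 to 0.71 and choroid plexus function from 0.46 to 0.83. Restricting lists to members with at least 50 UMIs gave no value for named genes, whose rule already asks for it, nor did size factors and pseudocounts for shares.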

Other observations

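No test in this part was set beforehand; all of these values were picked out only after the results had been seen.

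Sub-cluster 8 of the Cajal-Retzius-like neurons held cells of both genotypes (36, 29 and 23), as did sub-cluster 0 (24, 20 and 528). The knockout cells of sub-cluster 8 kept Lhx1 at 430 [330 to 552] CPM, against 659 and 714 in the wild type, and Reln at 111 against 174 and 121, although Trp73 had 0 [0 to 25.6] CPM (241 and 234 in the wild type) and Cdkn1a 0 (555 and 743). In sub-cluster 0, which held most knockout cells, their Lhx1 stood at 11.6 CPM and Reln at 156. Intermediate progenitor-like cells of the knockout had higher Lhx1 (4.18-fold [3.40 to 5.17], a difference that turned around under other class borders), Onecut2 (18.1, 19.4 and 73.3 CPM) and Reln (6.53, 4.51 and 25.2), and the Cajal-Retzius identity list had a median of 0.53 there (percentile 100; −0.53 to 0.79 over other settings). In hem progenitor-like cells Eomes, a T-box factor of intermediate progenitors (5.02, 6.33 and 29.5), Trpm3 (13.7, 12.1 and 83.8) and Eya4 (4.79, 4.81 and 49.5) were higher in the knockout.

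Some unnamed clusters were nearly particular to the knockout. Cluster 17 (0, 1 and 240 cells) had the signalling genes Fgf17, Fgf8 and Fgf18 among its top genes, and cluster 10 (61, 61 and 1093 cells) the Wnt antagonist Sfrp1. The diencephalic-like cluster 19 (0, 0 and 109 cells) had Barhl2 and Olig3, while cluster 12, with Six3 and Lhx5, was richer in the wild type (424, 348 and 170). Whether the borders of the dissection or the genotype set these numbers was not tested.

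The lists not yet given for neurons had these medians: S phase −0.05, G2 and M phase −0.41, hem signalling −0.91, Notch −0.30, subplate 0.24, choroid plexus function 0.06, early timing −0.27, late timing 1.09, dissociation stress −0.32, hypoxia and glycolysis −0.05 and sex-linked genes −0.30. Haemoglobin genes were higher in the knockout in each class compared and in unnamed clusters, with medians from 3.1 in the neurons outside the Cajal-Retzius-like clusters to 4.71 in choroid plexus-like cells.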
